A study of Mus musculus with 4 samples.

How the data were processed

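The series measured messenger RNA in mouse tumour-associated macrophages by bulk RNA sequencing. Per the labels' design text, the cells were sorted from glioblastoma xenografts as CD45-positive, Gr1-negative, CD11b-positive and DAPI-negative after enzymatic dissociation of the tumours and lysis of red cells. The 4 libraries fall into 2 groups by their titles, 2 controls and 2 from treatment with MK-8931 (verubecestat, an inhibitor of the beta-secretase BACE1). The labels' protocols describe a treatment of 3 days and RNA taken from glioma stem cells, while their cell type and design entries name sorted macrophages. The groups were taken from the titles, and how the treatment reached the macrophages is not settled by the labels. The labels do not say that the libraries came from separate animals.

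Deposited values were read from a table with a row for each of 54532 mouse genes. Raw counts per gene were deposited by the authors as whole numbers, per the file headers. FPKM values, which are scaled to gene length and library size, were computed by the authors, per the file headers, and were checked to equal the count times a constant per library and gene length, so they were not tested separately. A further set of values was found to be the authors' deposited count divided by a factor per library, between 0.975 and 1.03. The authors' deposited table also holds their own log2 fold change, p-value and adjusted p for 22381 genes, with no test named in the header. The submitters' processing notes name CASAVA and the mouse build mm9. The coordinates in the file are nevertheless those of GRCm38: of 54495 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 53585 (98.3%) have the same chromosome, start and end. Coordinates are therefore given as GRCm38. The aligner, the counting tool and whether the counting used strand are not given in the sources used here. Reads from near-identical gene copies and from overlapping genes may have been split or shared by the counting.

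Library totals lay between 18257930 and 20179875 counts. A total of 30878 genes had no count in any library. A gene with no count in a library has a level of at most 0.149 to 0.164 CPM, the count scaled to library size, which is the level of 3 counts and covers counting error only. The counts of the 2 controls differed by more than sampling noise (chi-square per degree of freedom 29.7), as did those of the 2 MK-8931 libraries (17.1), so no library was taken for a second deposit of another.

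Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 13932 genes. Libraries were scaled by TMM (factors 0.971 to 1.01), and MK-8931 was compared with control by the quasi-likelihood F test with robust dispersions (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are TMM-scaled and given as mean ± SD. Log2 fold changes are fitted values, and their standard error (SE) is the absolute log2 fold change divided by the square root of F. Counts were simulated from these libraries with 200 changed genes, and 13511 genes were tested. The test recovered 8 of 63 genes changed 1.5-fold, 44 of 66 changed 2-fold and 53 of 64 changed 4-fold. It made 1 false call among 106. The simulation drew each gene independently at the trended dispersion, so these rates may be better than those in the real libraries.

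A set of 36 gene lists, covering macrophage states, signalling targets, metabolism, stress and the markers of other cell types that a sort could hold, was fixed before the data were examined, as were the test, the threshold, the rule for named genes and the alternatives unless stated. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 36 lists. The same test with a correlation estimated for each list, and fry, a rotation test of each list by itself, were run beside it. On simulated counts, 0 of 36 random lists passed and a planted list passed. The simulated genes vary independently, so this cannot show how often camera passes lists of correlated genes by mistake. For each list, members were counted past the threshold adjusted over all genes and adjusted over the list alone.

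Named genes were chosen by rule. The rule takes Bace1, then the 12 largest rises and the 12 largest falls among genes past the threshold with both treated libraries on the same side of both controls and a mean of at least 5 CPM, leaving out predicted loci, small RNAs, pseudogenes and receptor segments. It adds the 5 most abundant such genes in each direction. From each list it takes the 2 members with the smallest p in each direction that passed, or, where none passed, the 2 with the smallest p, given as values. Some genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen.

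The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, library size alone, no filter on low counts, a filter of 1 CPM in 2 libraries, a 2-fold threshold, the replicate number as a block, and leaving out each library in turn. With a library left out, the lone library of its group is assumed to vary like the other group. A further alternative, lists without the genes that neutrophils are known to express, was chosen after the data were seen. It leaves fewer genes in a list and cannot show which cells a rise came from. The alternatives planned for normalized values alone did not apply to counts. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for reading the table and for figures.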

Results

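Tumour-associated macrophages sorted from glioblastoma xenografts in mice were profiled by RNA sequencing after treatment with MK-8931, a small-molecule inhibitor of the beta-secretase BACE1, or without it. Each group held 2 libraries. The total count was 18389023 for control 1, 20179875 for control 2, 19325817 for MK-8931 1 and 18257930 for MK-8931 2. Between 18258 and 20075 genes were detected per library. Mitochondrial transcripts took 1.10% to 1.38% of counts. Cathepsin B (Ctsb), a lysosomal protease, was the most abundant gene in each library at 1.05% to 1.27%. The comparison asks how macrophage gene expression differed with the inhibitor. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Gene-level adjusted p-values below are from edgeR's quasi-likelihood test and list-level ones from camera.

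In the MK-8931 libraries, 120 of 13932 genes rose and 19 fell. Among the named genes, the 5 largest rises were in markers of neutrophils. Cxcr2, a receptor for neutrophil-attracting chemokines, went from 1.19 ± 0.526 to 63.8 ± 15.1 CPM. Other rises were smaller, such as that of Il1b, which encodes interleukin-1 beta, from 36.4 ± 8.99 to 342 ± 109 CPM (mean ± SD, n = 2). Of 9 tested MHC class II genes 2 rose as well, with H2-Ab1 at 30.8 ± 7.22 CPM in controls and 79.9 ± 15.4 CPM with MK-8931. The falls were smaller, with a median log2 fold change of −0.97 against 2.06 for the rises. They included Fkbp5, a glucocorticoid-induced co-chaperone, which went from 235 ± 36.7 to 110 ± 0.054 CPM. Of the rises, 108 were at least 2-fold and 61 at least 4-fold, and 9 of the falls were at least 2-fold.

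Bace1, the gene of the drug's target (ENSMUSG00000032086, chromosome 9, 45838580 to 45864399, GRCm38, plus strand), was expressed at a low level in both groups. It stood at 9.48 ± 3.43 CPM in controls and 8.98 ± 0.295 CPM with MK-8931 (SD, n = 2), a log2 fold change of −0.08 (SE 0.29, adjusted p = 0.965). The control libraries set its direction, with a log2 fold change of 0.34 without control 1 and −0.41 without control 2. The list of BACE1, its substrates and the secretases of the amyloid precursor protein also held other genes, such as Sorl1, Apoe and Ide. Of its 19 tested genes, 0 passed over all genes. Adjusted over the list alone, 1 was higher and 1 lower. The smallest p-values belonged to Sorl1, a sorting receptor of the amyloid precursor protein (log2 fold change 0.85, SE 0.16, adjusted p = 0.0505), and Apoe, the apolipoprotein E gene (−0.59, SE 0.15, adjusted p = 0.141). The list as a whole was not past the threshold (median log2 fold change −0.08, adjusted p = 0.634).

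**Figure D1:**
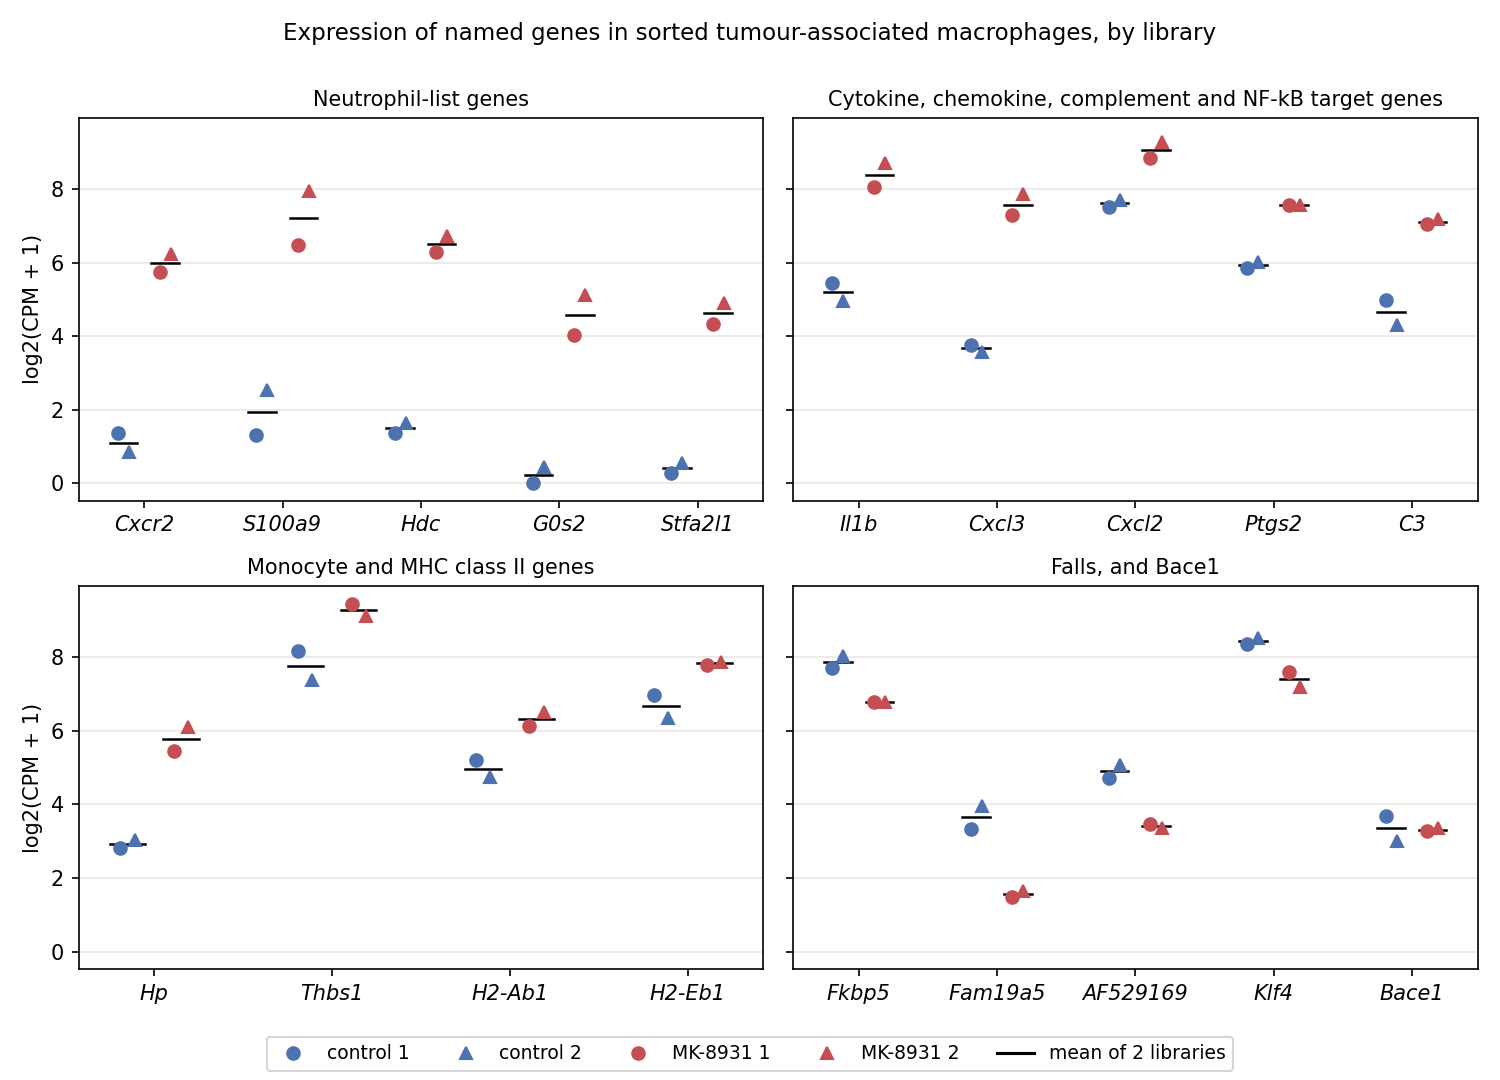
Expression of 19 named genes on a log2(CPM + 1) axis, with circles for replicate 1 and triangles for replicate 2 of each group, control in blue and MK-8931 in red, and a bar at the mean of the 2 plotted values. Both MK-8931 libraries lay above both controls for the 14 genes of the first 3 panels, below them for Fkbp5, Fam19a5, AF529169 and Klf4, and within the range of the controls for Bace1.

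Neutrophil markers rose together, although the sort selected cells negative for Gr1, an antigen of neutrophils and some monocytes. Of the 16 tested members of the neutrophil list, 13 rose and 0 fell, and 14 rose adjusted over the list alone. The median log2 fold change was 3.01 (adjusted p = 2.8e-97, and adjusted p = 0.191 with an estimated correlation). The 5 largest of the named rises were in it. Hdc, the histidine decarboxylase that makes histamine (chromosome 2, 126593667 to 126619299, minus strand), went from 1.83 ± 0.377 to 91.3 ± 19.3 CPM (log2 fold change 5.63, SE 0.25, adjusted p = 6.89e-05). Cxcr2 (chromosome 1, 74153989 to 74161246, plus strand) rose by a log2 fold change of 5.74 (SE 0.31, adjusted p = 1.41e-04). G0s2, an inhibitor of triglyceride breakdown, had 0 and 7 counts in the controls and 299 and 628 with MK-8931. Its log2 fold change of 7.03 (SE 0.70, adjusted p = 0.00247) depended on which library was left out, at 6.08 without control 1 and 6.33 without MK-8931 2. Without control 2 the remaining control had 0 counts, so no fold is given. With limma-voom the call was lost (adjusted p = 0.139). Stfa2l1, of the stefin A cluster of near-identical genes, had a log2 fold change of 6.12 (SE 0.40, adjusted p = 5.37e-04), or 6.76 without control 2. Its value is uncertain because its reads may be shared with its copies. S100a9, a subunit of calprotectin, was at 1.51 and 4.85 CPM in the controls and 87.8 and 248 CPM with MK-8931. Its call (adjusted p = 0.00848) was lost without control 1 (0.495), without control 2 (0.837) and without MK-8931 2 (0.0623), and also with limma-voom (0.0841) and with no filter on low counts (0.552). Its log2 fold change of 5.71 (SE 0.64) was 5.10, 6.79 and 4.76 with those 3 libraries left out. Outside the lists, Asprv1, a protease gene (log2 fold change 4.89), Il1f9, the interleukin-36 gamma gene (4.45), Dennd3 (4.21) and Upp1, uridine phosphorylase (4.03), also rose (adjusted p from 8.4e-04 to 0.00729). These folds moved most for Il1f9, to 3.72 without control 1 and 6.06 without control 2, for Asprv1, to 5.71 without control 2, and for Upp1, to 4.87 without control 1. Together the 21 listed neutrophil genes took 0.0503% and 0.0445% of counts in the controls and 0.132% and 0.206% in the MK-8931 libraries. Most of the control share was Mmp9, a gene also in other lists (0.0379% and 0.0338%, against 0.0637% and 0.0945% with MK-8931). The other 20 took 0.0124% and 0.0107% in the controls and 0.0684% and 0.111% with MK-8931.

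Some cytokine and chemokine genes rose alongside these markers. Of 21 tested genes of classical (M1-like) activation, 4 rose and 0 fell (8 higher and 2 lower adjusted over the list alone). The median log2 fold change was 0.33 (adjusted p = 4.41e-08, and adjusted p = 0.214 with an estimated correlation). The 4 rises included Il1b (log2 fold change 3.23, SE 0.25, adjusted p = 8.4e-04, and 0.214 with the replicate number as a block). They also included Ptgs2, which encodes the prostaglandin synthase COX-2 (1.65, SE 0.13, adjusted p = 8.4e-04). The other two, chosen after their values were seen, were Nos2, the inducible nitric oxide synthase (1.91, SE 0.20, adjusted p = 0.00353), and the formyl peptide receptor Fpr2 (2.59, SE 0.30, adjusted p = 0.00512). Tnf, of the same list and chosen after its value was seen, had a log2 fold change of −0.95 (adjusted p = 0.0605). Among 23 NF-kB target genes, 4 rose and 0 fell (14 higher and 2 lower adjusted over the list alone). The median was 0.42 (adjusted p = 2.47e-16, and adjusted p = 0.191 with an estimated correlation). Among 27 chemokines and their receptors, 4 rose and 0 fell (8 higher and 1 lower adjusted over the list alone). The median was 0.21 (adjusted p = 3.13e-08, and adjusted p = 0.389 with an estimated correlation). Cxcl3, a neutrophil attractant, rose from 11.8 ± 1.18 to 194 ± 52.0 CPM (log2 fold change 4.04, SE 0.22, adjusted p = 1.41e-04), and Cxcl2, with the same action, from 195 ± 16.6 to 542 ± 114 CPM. Of 27 genes of interleukin-6 signalling and STAT3 targets, 1 rose and 0 fell (7 higher and 0 lower adjusted over the list alone). The median was 0.21 (adjusted p = 1.39e-04, and adjusted p = 0.443 with an estimated correlation). The gene that rose was Lcn2, an iron-scavenging protein also stored in neutrophil granules, at 1.23 ± 0.140 CPM in controls and 34.4 ± 12.2 CPM with MK-8931. The neutrophil list moved with these 4 lists, with 13 of its 16 genes higher. Without control 2 the medians were 0.16 for the M1-like list, 0.39 for chemokines and 0.06 for interleukin-6 and STAT3, the last at 0.34 without control 1. Without MK-8931 1 they were 0.54 for the M1-like list, 0.35 for chemokines and 0.14 for interleukin-6 and STAT3, and without MK-8931 2 the chemokine median was 0.12. Each of these 4 list calls was lost without the genes neutrophils are known to express, an alternative chosen after the data were seen. The median was then 0.02 for the 13 M1-like genes left (adjusted p = 0.890, test direction lower) and 0.21 for 5 NF-kB targets (0.697). It was 0.09 for 18 chemokine genes (0.165) and 0.06 for 20 interleukin-6 and STAT3 genes (0.606). The loss does not show a neutrophil source, since the setting left only 5 of 23 NF-kB targets and 13 of 21 M1-like genes. Control cells also expressed genes of these lists, such as Cxcl2 at 195 CPM.

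Monocyte and MHC class II genes were higher as lists with the preset correlation. In the list of monocytes and monocyte-derived macrophages, 6 of 20 tested genes rose and 1 fell (9 higher and 1 lower adjusted over the list alone). The median log2 fold change was 0.49 (adjusted p = 8.58e-12, and adjusted p = 0.191 with an estimated correlation). Without the genes neutrophils express, the alternative chosen after the data were seen, it was 0.13 over 10 genes and the call was lost (0.165). Hp, which encodes haptoglobin, had a log2 fold change of 3.05 (SE 0.25, adjusted p = 8.87e-04). Ccr2, the receptor that brings monocytes into tissue and a gene chosen after its value was seen, rose from 54.5 ± 20.5 to 139 ± 8.45 CPM (adjusted p = 0.0359). Lyz1, a lysozyme gene with a close copy in Lyz2, was the member that fell (−1.27, SE 0.22, adjusted p = 0.0360), a call lost without MK-8931 1 (0.0700) or MK-8931 2 (0.0754). For MHC class II, 2 of 9 tested genes rose and 0 fell (5 higher and 0 lower adjusted over the list alone). The median was 0.89 (adjusted p = 8.0e-07, and adjusted p = 0.389 with an estimated correlation). H2-Ab1 had a log2 fold change of 1.37 (SE 0.21, adjusted p = 0.0205), and H2-Eb1 1.14 (SE 0.20, adjusted p = 0.0360). The call for H2-Eb1 was lost without MK-8931 2 (0.0546) and with library size alone (0.0524). The other members were chosen after their values were seen. Some lay near 0 or below, with log2 fold changes of 0.04 for H2-DMa, 0.16 for H2-DMb1, 0.13 for H2-DMb2 and −0.63 for H2-Ob (adjusted p from 0.737 to 0.964). Ciita (1.43), Cd74 (1.11) and H2-Aa (0.89) were higher in both MK-8931 libraries than in both controls, but did not pass over all genes (adjusted p from 0.0583 to 0.112). In contrast, 0 of 18 genes of MHC class I presentation passed (median −0.02, adjusted p = 0.634). Markers of dendritic cells moved with these groups. Of 15 tested genes, 1 rose and 0 fell (7 higher and 0 lower adjusted over the list alone). The median was 0.97, or 0.55 without MK-8931 2 (adjusted p = 1.1e-06, and adjusted p = 0.224 with an estimated correlation). That gene was the chemokine Ccl22 (log2 fold change 1.78, SE 0.30, adjusted p = 0.0323, and 0.0870 without MK-8931 1). The neutrophil list, with 13 of 16 genes higher, moved with them as well.

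The platelet chemokine genes Pf4 and Ppbp also rose. Of the 3 tested genes of the red cell and platelet list, 2 rose, over all genes and adjusted over the list alone. The median was 1.08 (adjusted p = 3.62e-05, and adjusted p = 0.275 with an estimated correlation). With no filter on low counts the median was −0.04 and the list was not past the threshold (adjusted p = 0.114). Itga2b, the gene of the list that did not pass and one chosen after its value was seen, had a log2 fold change of −0.03 (adjusted p = 0.996). Pf4, also made by macrophages, went from 162 ± 6.97 to 343 ± 63.0 CPM (adjusted p = 0.0139, and 0.0659 without MK-8931 2), and Ppbp from 4.08 ± 3.67 to 36.5 ± 5.53 CPM (adjusted p = 0.0337). The call for Ppbp was lost without MK-8931 1 (0.438) and without MK-8931 2 (0.589), and its log2 fold change of 3.17 became 4.61 without control 1 and 2.45 without control 2. With the replicate number as a block the Ppbp call was also lost (adjusted p = 0.374). Neutrophil markers were higher in the MK-8931 libraries too (13 of 16).

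**Figure D2:**
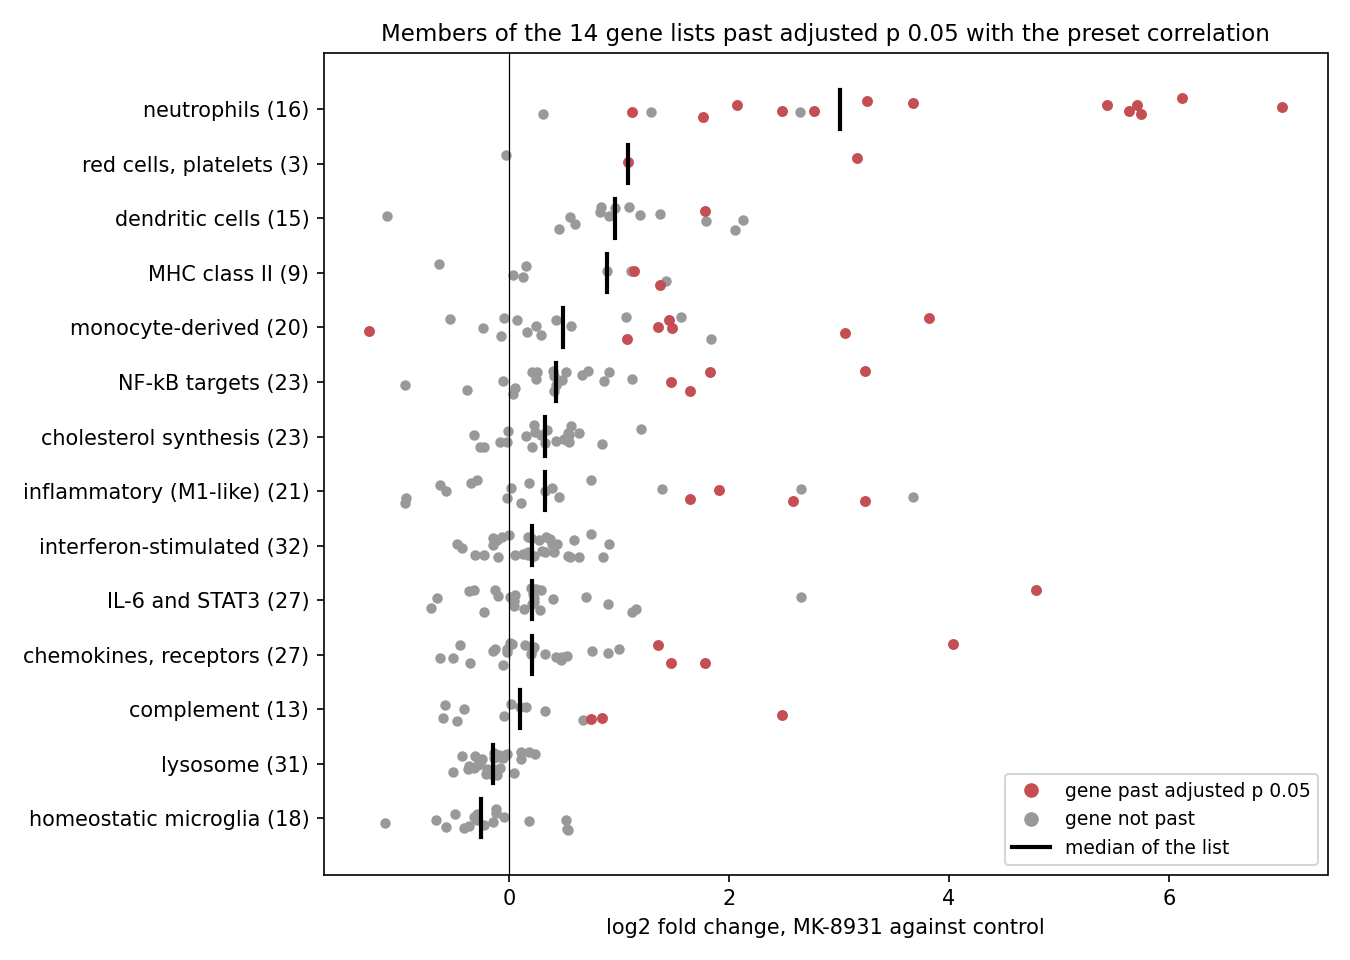
Log2 fold changes, MK-8931 against control, of the tested members of the 14 gene lists past the threshold with the preset correlation, with the number tested in brackets, genes past adjusted p 0.05 in red and the list median as a bar. Of the 16 neutrophil genes, 13 are red, while the homeostatic microglia, lysosome, interferon and cholesterol lists have no red gene.

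Genes of tumour-supportive macrophages and of matrix remodelling moved in both directions. Of 26 tested tumour-supportive (M2-like) genes, 3 rose and 0 fell, and 8 were higher and 4 lower adjusted over the list alone. The median was 0.16, and the list was not past the threshold (adjusted p = 0.0504). It passed without control 2 (0.00312) and with no filter on low counts (0.0274), both at the preset correlation. With all libraries and an estimated one its adjusted p was 0.443. Its median was 0.37 without control 1, 0.07 without MK-8931 1 and −0.06 without the genes neutrophils express, the alternative chosen after the data were seen. Chil3, a chitinase-like lectin, went from 35.9 ± 5.96 to 119 ± 34.1 CPM (adjusted p = 0.00794). Mmp9, the gelatinase gene, which is also in the neutrophil list, went from 362 ± 19.0 to 785 ± 217 CPM (adjusted p = 0.0315, and 0.137 without MK-8931 2). Among 29 genes of matrix remodelling and growth factors, 4 rose and 2 fell (8 higher and 7 lower adjusted over the list alone). The list was not past the threshold (median 0.20, adjusted p = 0.242). Its median was 0.34 without control 1, 0.08 without control 2 and 0.09 without MK-8931 2, and also 0.09 without the genes neutrophils express. The rises included Mmp13, a collagenase (log2 fold change 1.35, SE 0.17, adjusted p = 0.00768), and Mmp12, the macrophage elastase (1.14, SE 0.16, adjusted p = 0.0141, and 0.0722 without MK-8931 2). Thbs1, the thrombospondin-1 gene, went from 226 ± 86.6 to 632 ± 101 CPM (adjusted p = 0.0300). Hgf, hepatocyte growth factor, fell from 70.6 ± 1.35 to 37.5 ± 1.45 CPM (adjusted p = 0.0223, lost without MK-8931 1 at 0.0716 and without MK-8931 2 at 0.133). In the complement list, 3 of 13 genes rose and 0 fell (4 higher and 4 lower adjusted over the list alone). The median was 0.10 (adjusted p = 0.0458, and adjusted p = 0.443 with an estimated correlation). The list was not past the threshold without control 1 (median 0.07, adjusted p = 0.241), without MK-8931 2 (0.05, adjusted p = 0.120), with library size alone (0.0539) or with no filter (0.114). Its median was 0.17 without control 2, and −0.22 without the genes neutrophils express (8 genes, adjusted p = 0.165). With the replicate number as a block the complement call was lost as well (adjusted p = 0.0641). C3, the central complement component, rose from 24.8 ± 8.33 to 138 ± 10.4 CPM (log2 fold change 2.48, SE 0.22, adjusted p = 0.00121). Cfp, which encodes properdin, rose from 166 ± 2.63 to 298 ± 27.0 CPM (adjusted p = 0.0205, and 0.170 without MK-8931 2). Of 12 checkpoint and immunosuppressive genes, 1 rose and 0 fell (3 higher and 1 lower adjusted over the list alone). It was the inhibitory sialic acid receptor Siglece (log2 fold change 1.55, SE 0.27, adjusted p = 0.0365, and 0.0651 without MK-8931 2). The list median was 0.18 (adjusted p = 0.0881). That list passed as higher without control 1 (median 0.29, adjusted p = 0.0387), without MK-8931 1 (0.0432) and with no filter (0.0280), at the preset correlation. With all libraries and an estimated one its adjusted p was 0.463. These changes stood beside the neutrophil list, with 13 of 16 genes higher, and the dendritic list, with a median of 0.97.

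Microglial and lysosomal genes were lower as lists, with no homeostatic or lysosomal gene past the threshold. Of 18 tested homeostatic microglia genes, 0 passed over all genes and 3 were lower adjusted over the list alone. Of the 18 log2 fold changes, 14 were below 0, and the median was −0.26, or −0.13 without control 2 (adjusted p = 9.92e-04, and adjusted p = 0.513 with an estimated correlation). Gpr34, a lysophospholipid receptor, stood at 141 ± 48.4 CPM in controls and 64.3 ± 8.81 CPM with MK-8931 (adjusted p = 0.0609), and P2ry12, a purinergic receptor of microglia, at 102 ± 17.3 and 64.2 ± 1.69 CPM (adjusted p = 0.113). Of 31 lysosomal genes, 0 passed by either adjustment and 26 were below 0. The median was −0.15 (adjusted p = 0.00348, and adjusted p = 0.780 with an estimated correlation). That list was not past the threshold without control 2 (median −0.07, adjusted p = 0.351) or without MK-8931 1 (−0.16, adjusted p = 0.0766). Its median was −0.23 without control 1. The smallest p-values were those of Ctsd, cathepsin D (log2 fold change −0.43, SE 0.14, adjusted p = 0.281), and Scarb2, the receptor that sorts glucocerebrosidase (−0.37, SE 0.12, adjusted p = 0.283). Of 19 genes of activated microglia, Lpl, the lipoprotein lipase gene, rose (0.72, SE 0.12, adjusted p = 0.0360, lost without MK-8931 1 at 0.159 and without MK-8931 2 at 0.242) and 0 fell. Adjusted over the list alone, 2 were higher and 2 lower, and the list median was −0.19 (adjusted p = 0.179). The activated list passed as lower without control 1 (−0.31, adjusted p = 5.25e-04), without MK-8931 2 (−0.25, adjusted p = 0.0244) and without the genes neutrophils express (−0.35, adjusted p = 0.0309), the alternative chosen after the data were seen. These 3 used the preset correlation, and with all libraries and an estimated one the adjusted p was 0.860. Without control 2 its median was −0.05. In the same libraries 13 of 16 neutrophil genes were higher, and the dendritic list had a median of 0.97.

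Cholesterol synthesis and interferon-stimulated genes were higher as lists, again with no gene past the threshold over all genes. Of 23 cholesterol synthesis and SREBP2 target genes, 0 passed, and 8 were higher and 0 lower adjusted over the list alone. The median was 0.33, or 0.18 without MK-8931 2 (adjusted p = 1.9e-04, and adjusted p = 0.513 with an estimated correlation). Of 32 interferon-stimulated genes, 0 passed, and 4 were higher and 0 lower adjusted over the list alone. The median was 0.21 (adjusted p = 0.00483, and adjusted p = 0.513 with an estimated correlation). The interferon list was not past the threshold without control 2 (adjusted p = 0.0932). Oasl2 had a log2 fold change of 0.86 (SE 0.16, adjusted p = 0.0517) and Ifitm3 of 0.64 (SE 0.14, adjusted p = 0.0879). The neutrophil list (13 of 16 genes higher, median 3.01) and the dendritic list (median 0.97) moved with both. Without the genes neutrophils express, the alternative chosen after the data were seen, both lists stayed past the threshold (adjusted p = 5.97e-04 for cholesterol and 0.0298 for interferon).

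The falls by the largest fold were in Fam19a5, a secreted chemokine-like protein (log2 fold change −2.59, SE 0.34, adjusted p = 0.00988), AF529169 (−1.57, SE 0.20, adjusted p = 0.00898), and Npnt, the matrix protein nephronectin (−1.63, SE 0.28, adjusted p = 0.0365). Adarb1, an RNA-editing enzyme gene, fell from 21.1 ± 4.67 to 7.82 ± 1.40 CPM, and the metalloprotease gene Adamts1 from 28.0 ± 2.19 to 12.4 ± 0.0605 CPM. Among abundant genes, Fkbp5 (chromosome 17, 28399094 to 28517527, minus strand) fell by 1.09 on the log2 scale (SE 0.14, adjusted p = 0.00990), and Klf4, a zinc-finger transcription factor gene, by 1.03 (SE 0.16, adjusted p = 0.0226). Plk2, a stress-induced kinase gene, went from 489 ± 59.5 to 257 ± 44.7 CPM (adjusted p = 0.0355), and Hist1h1c, a linker histone gene, from 261 ± 26.0 to 160 ± 0.866 CPM (adjusted p = 0.0460). Adam19, a metalloprotease gene, fell by 1.03 on the log2 scale (adjusted p = 0.0247). Of the genes in this paragraph, Adarb1, Adamts1 and Hist1h1c were not past the threshold without MK-8931 1 (adjusted p from 0.0602 to 0.210). Npnt, Adamts1, Klf4, Adam19, Plk2 and Hist1h1c were not past it without MK-8931 2 (0.0571 to 0.272), nor was Hist1h1c with library size alone (0.0526).

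Stress genes that tissue dissociation can induce were divided. Of 31 immediate-early and heat-shock genes, 2 rose and 1 fell (4 higher and 8 lower adjusted over the list alone). The list had a median of −0.02, a mean of 0.03 and a test direction of lower (adjusted p = 0.393). It passed as lower without MK-8931 1 (median −0.15, adjusted p = 0.0141) at the preset correlation, while with all libraries and an estimated one the adjusted p was 0.877. Hspa1b and Hspa1a, which encode the inducible heat-shock protein HSP70, rose to 1309 ± 204 from 411 ± 205 CPM (adjusted p = 0.0460) and to 506 ± 70.1 from 169 ± 80.9 CPM (adjusted p = 0.0454). These 2 genes are near-identical copies, so their separate values are uncertain. Their calls were lost without MK-8931 1 (both 0.219), without MK-8931 2 (0.185 and 0.190), with DESeq2 (0.0584 and 0.0606) and with library size alone (0.0558 and 0.0590). That for Hspa1b was also lost with a filter of 1 CPM in 2 libraries (0.0528). The log2 fold change of Hspa1b moved from 1.67 to 2.29 without control 1. Klf4 was the gene that fell.

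Other lists were not past the threshold. Of 17 macrophage identity genes, only Itgam, the CD11b gene used in the sort, rose (log2 fold change 0.75, SE 0.14, adjusted p = 0.0485, lost without MK-8931 1 at 0.122, without MK-8931 2 at 0.248, with library size alone at 0.0599 and with upper-quartile scaling at 0.0523). Adjusted over the list alone, 2 were higher and 0 lower. That list had a median of −0.04, a mean of 0.05 and a test direction of higher (adjusted p = 0.762). Itgam was also the only call among 32 phagocytosis genes (2 higher adjusted over the list alone). The list had a median of −0.06, a mean of 0.03 and a test direction of lower (adjusted p = 0.805). Lpl was the only call among 21 genes of lipid handling (2 higher and 2 lower adjusted over the list alone). The list had a median of −0.07, a mean of 0.06 and a test direction of lower (adjusted p = 0.869). No gene passed over all genes, and none adjusted over the list alone, among 33 cell cycle genes (median −0.03, adjusted p = 0.331), 22 hypoxia genes (−0.06, adjusted p = 0.595) and 20 glycolysis genes (0.06, adjusted p = 0.805). The same held for 34 respiratory chain genes (−0.11, adjusted p = 0.0904) and 30 ribosomal protein genes (−0.02, adjusted p = 0.770). The direction of these last 2 lists followed the library left out. Both took less of the counts in replicate 1 than in replicate 2 of each group. Respiratory chain genes took 0.378% and 0.479% in controls 1 and 2, and 0.374% and 0.438% in MK-8931 1 and 2. For ribosomal proteins these were 1.29%, 1.68%, 1.34% and 1.67%. Leaving out 1 library unbalances the replicate numbers between the groups, so the turns followed the number, whose meaning the labels do not give. The respiratory chain passed as lower without control 1 (−0.33, adjusted p = 1.8e-08), without MK-8931 2 (−0.25, adjusted p = 9.92e-05) and with no filter (0.0486), and as higher without control 2 (0.15, adjusted p = 0.0296). Ribosomal proteins passed as lower without control 1 (−0.25, adjusted p = 1.07e-04) and without MK-8931 2 (−0.20, adjusted p = 0.00372), and as higher without control 2 (0.24, adjusted p = 1.51e-04). The cell cycle list passed as lower without control 1 (−0.12, adjusted p = 0.0246). These calls all used the preset correlation of 0.01. The correlation estimated from all libraries was 0.92 for the respiratory chain, 0.976 for ribosomal proteins and 0.173 for the cell cycle, and with it the adjusted p was 0.877, 0.940 and 0.873. Of 18 genes of the unfolded protein response, 0 passed over all genes and 1 was lower adjusted over the list alone (median 0.04, mean 0.00, test direction lower, adjusted p = 0.674). Among these lists, the genes with the smallest p-values were Higd1a (log2 fold change −0.56, adjusted p = 0.276) and Egln3 (0.49, adjusted p = 0.255) for hypoxia and Ppp1r15a (−0.80, adjusted p = 0.0505) for the unfolded protein response.

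Markers of cell types outside the myeloid lineage were mostly too low to test, except in the vascular list. No gene passed over all genes among 4 tested of T and NK cells (median 0.27, mean 0.29, test direction lower, adjusted p = 0.805), 5 of B cells (0.37, adjusted p = 0.275) and 9 of astrocytes and glioma (−0.42, adjusted p = 0.426). Nor did any among 3 of oligodendrocytes (−0.08, adjusted p = 0.598), 3 of neurons (1.54, adjusted p = 0.0794) and 17 of vessels and fibroblasts (0.46, adjusted p = 0.160). The tumours were xenografts and only mouse genes were counted. Whether reads of tumour cells would be counted was not tested, so the glioma markers do not show whether tumour cells were carried over. The vascular list passed as higher without control 1 (0.18, adjusted p = 0.00103), at the preset correlation (adjusted p = 0.555 with all libraries and an estimated one). Its median was 0.29 without control 2, 0.18 without MK-8931 1 and 0.12 without MK-8931 2. The medians of other lists also depended on the library left out. For B cells it was 0.67 without control 1, −0.10 without control 2 and 0.08 without MK-8931 2. For T and NK cells it was 0.11 without control 1, 0.44 without control 2, −0.25 without MK-8931 1 and 0.58 without MK-8931 2. For glia it was −0.02 without control 2. For oligodendrocytes it was −0.13 without control 1, −0.14 without control 2, −0.02 without MK-8931 1 and −0.21 without MK-8931 2. Adjusted over the list alone, 1 T or NK gene was lower, 1 B cell gene higher, 2 glial genes higher and 3 lower, 2 neuronal genes higher and 1 vascular gene higher. Pecam1, an endothelial gene, stood at 7.74 ± 4.37 CPM in controls and 22.3 ± 2.48 CPM with MK-8931 (adjusted p = 0.0993), and Nes, a progenitor gene, at 123 ± 4.67 and 77.3 ± 11.5 CPM (adjusted p = 0.0872).

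At an unadjusted p below 0.05, 910 genes were higher and 592 lower. In the authors' deposited table, 242 genes were higher and 94 lower at an adjusted p below 0.05, and 136 of the 139 genes called here were among them with the same sign. Both groups separated without overlap for 41.2% of tested genes, against 33.3% expected by chance for 2 libraries against 2. None of the 14 list calls held with an estimated correlation or with fry, which gave 0 lists past the threshold. The estimated correlation was below the preset 0.01 for the M1-like (−0.029), NF-kB (−0.024), monocyte (−0.044), complement (−0.017), dendritic (−0.012) and red cell and platelet (−0.429) lists. In these lists a higher correlation cannot explain the loss. In the others it was higher, up to 0.532 for the lysosome. That setting rests on the few residual degrees of freedom of 4 libraries, so a lost call says little. The number of calls depended on which library was left out, with 520 genes higher and 243 lower without control 1, 174 and 47 without control 2, 128 and 23 without MK-8931 1, and 85 and 10 without MK-8931 2, the last keeping 77 of the 120 rises and 4 of the 19 falls.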

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

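The alternative that takes out the genes neutrophils are known to express was chosen only after the results were seen, and the others were planned. None of the 139 called genes changed sign when a library was left out. This was all but fixed in advance, since for each of them both treated libraries lay on the same side of both controls. The count of higher and lower genes was 246 and 98 with DESeq2 and 366 and 176 with no filter on low counts, and the lower count was 30 with limma-voom and 9 with a 2-fold threshold, which removes the smaller changes by construction. RLE scaling gave 120 and 19, and with library size alone 110 of the 120 higher and 15 of the 19 lower genes remained. Leaving out a library gave 85 to 520 higher and 10 to 243 lower genes, with fewer samples in each fit. With the replicate number as a block, a paired fit, the counts were 468 and 275, and 114 of the 120 higher and 19 of the 19 lower genes remained. The labels do not say what a shared number means, and the differences between replicates 1 and 2 had a correlation of 0.403 between the groups across 9131 genes, which are not independent replicates. Of 47 named genes past the threshold, 23 stayed past it whichever library was left out, 46 without control 1 and also without control 2, 35 without MK-8931 1 and 25 without MK-8931 2. With all 4 libraries, named genes lost their call with limma-voom (G0s2, adjusted p = 0.139, and S100a9, 0.0841), no filter (S100a9, 0.552), DESeq2 (Hspa1b, 0.0584, and Hspa1a, 0.0606), upper-quartile scaling (Itgam, 0.0523) and a filter of 1 CPM (Hspa1b, 0.0528). Library size alone lost 5 (adjusted p from 0.0524 to 0.0599) and the 2-fold threshold 8. With the block, Il1b (0.214), Ppbp (0.374) and the complement list (0.0641) were not past the threshold, while the tumour-supportive (0.0393) and respiratory chain (0.0327) lists were. The number of lists past the threshold fell from 14 to 0 with an estimated correlation, to 0 with fry and to 7 without genes neutrophils express. With that last setting the median log2 fold change became 0.021 for the M1-like list, −0.224 for complement, −0.059 for tumour-supportive, −0.107 for macrophage identity and 0.044 for glycolysis, and in these 5 the test direction turned. The MHC class II (0.89), dendritic (1.03), homeostatic microglia, lysosome, cholesterol and interferon lists stayed past the threshold. Activated microglia newly passed as lower (−0.347, adjusted p = 0.0309). The NF-kB, chemokine, monocyte and interleukin-6 lists were no longer past it, and the red cell and platelet list kept too few genes to test. Directions that turned were otherwise those of lists and genes not past the threshold. With fry they were phagocytosis (median −0.056) and lipid handling (−0.066), and with no filter T and NK cells (0.737). With a library left out, medians lay between −0.10 and 0.005 for macrophage identity, −0.093 and 0.03 for MHC class I, −0.079 and 0.005 for phagocytosis, −0.309 and −0.054 for activated microglia, −0.121 and 0.052 for the cell cycle and 0.015 and 0.067 for glycolysis. They lay between −0.325 and 0.151 for the respiratory chain, −0.036 and 0.016 for lipid handling, −0.044 and 0.043 for the unfolded protein response and −0.152 and 0.04 for immediate-early genes. They lay between −0.245 and 0.241 for ribosomal proteins, −0.254 and 0.576 for T and NK cells and −0.404 and −0.023 for astrocytes and glioma. Without control 2 the respiratory chain (adjusted p = 0.0296) and ribosomal protein (1.51e-04) lists passed as higher, and both passed as lower without control 1 (1.8e-08 and 1.07e-04) and without MK-8931 2 (9.92e-05 and 0.00372). The log2 fold change lay between −0.41 and 0.34 for Bace1, −0.54 and 0.14 for Rplp1, −0.016 and 0.73 for Cd79b and −0.22 and 0.063 for Cnp. The cause was not tested except where stated. At this depth the simulated recovery was 12.7% for 1.5-fold changes, 66.7% for 2-fold and 82.8% for 4-fold, so smaller changes were mostly not detectable.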

Other observations

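The gene choices and the tests of explanations in this part were made only after the results were seen. Some of the calls share a gene family, and the families were picked after their values were seen; Fpr2, Stfa2l1 and BC100530 among them are also in the fixed lists. Of 8 tested Clec4 genes, a cluster of C-type lectin receptors of myeloid cells, 4 rose and 0 fell, among them Clec4e, the receptor Mincle, from 55.4 to 152 CPM (log2 fold change 1.45, SE 0.19, adjusted p = 0.0103), and Clec4d (1.46, SE 0.24, adjusted p = 0.0311). Of 3 Sirpb1 genes 2 rose and of 8 Slfn genes 2 rose, with Slfn4 at 46.5 CPM in controls and 181 CPM with MK-8931 (adjusted p = 0.0114). Both formyl peptide receptors tested, Fpr1 and Fpr2, rose 5.00-fold and 6.0-fold. In the stefin A cluster 4 of 5 tested genes rose. Members of the Sirpb1, Slfn and stefin A clusters are close copies, so the counting may have shared their reads and their single values are uncertain. The long non-coding RNAs Mirt1 and Mirt2 and the receptor gene Mrgpra2b had 0 counts in both controls, and were at least 52.0-fold, 50.6-fold and 33.9-fold higher with MK-8931, against a floor of 3 counts over the control group.

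Enzymes and secreted factors in the same set of calls included Ptges, the prostaglandin E synthase that acts after COX-2, which rose 6.87-fold (SE 0.22 on the log2 scale, adjusted p = 8.4e-04), while Ptgs1 had a log2 fold change of 0.29 (adjusted p = 0.594). Acod1, which makes itaconate, rose from 6.36 to 66.2 CPM (adjusted p = 5.74e-04), and the cystine transporter gene Slc7a11 from 7.21 to 33.5 CPM (adjusted p = 9.47e-04), with its partner subunit Slc3a2 at a log2 fold change of −0.08 (adjusted p = 0.887). The coagulation factor genes F10 and F7 rose 3.29-fold and 3.04-fold (adjusted p = 0.00109 and 0.00729). Met, the receptor of hepatocyte growth factor, rose 4.76-fold (adjusted p = 0.00118), while its ligand gene Hgf fell by 0.92 on the log2 scale (adjusted p = 0.0223). These values are from edgeR with 2 libraries per group. In the same libraries 13 of 16 tested neutrophil genes were higher. Which cells the rises here and in the gene families above came from was not tested.

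The rise of neutrophil genes in a Gr1-negative sort, which should remove neutrophils, was weighed first. Depth is argued against, since the largest log2 ratio of an MK-8931 to a control total was 0.072 and the unscaled counts of the 16 genes had a median log2 ratio of 2.98 (SD 2.06), and basophils or mast cells as the source of Hdc are too, since 0 of 10 of their marker genes reached 1 CPM in both MK-8931 libraries and the highest value was 0.673 CPM. A candidate explanation is that more neutrophils with little Gr1 passed the gate. Of 16 tested markers 13 rose, with S100a9 at 168, Hdc at 91.3 and Cxcr2 at 63.8 CPM. The 5 untested ones stayed at few counts with MK-8931, at 0 and 14 for Ly6g, a gene of the Gr1 antigen. Camp had 0 and 3, Ngp 5 and 7, Elane 0 and 0 and Mpo 17 and 5. These low counts do not decide, since which of these genes such neutrophils transcribe was not tested. Expression of the same genes in monocytes or macrophages cannot be told apart from such neutrophils, because both would raise the same 16 tested genes. Of these, 4 were already at 10 CPM or more in control macrophages and 1, Mmp9, is in another list. How many of the inflammatory calls, such as Il1b and Cxcl3, share that source stays open.

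The second pattern is higher values of MHC class II and monocyte genes beside lower values of homeostatic microglia genes. A general interferon-gamma response across the sorted cells is argued against, since it should raise MHC class I presentation too. The 18 genes of that list had a median log2 fold change of −0.019 (SD of members 0.146) against 0.892 for MHC class II. The interferon-stimulated list, though, had a median of 0.21. Some class I genes, such as B2m at 1854 CPM, stood far above H2-Ab1 at 30.8 CPM in the controls. A response in a small part of the cells might therefore not show in class I, and was not tested. A lower share of microglia among the sorted cells may contribute: 6 of 8 tested microglia-restricted genes had log2 fold changes below 0 (median −0.49), but 0 passed the threshold and the 2 above 0, Siglech and Slc2a5, lay near the floor. The lower values were uneven. Tmem119, at 192 and 217 CPM in the controls, had −0.12 (SE 0.14) against −1.13 (SE 0.23) for Gpr34 and −0.84 (SE 0.16) for Adgrg1. Between them lay P2ry12 (−0.66, SE 0.16), Fcrls (−0.58, SE 0.14) and Olfml3 (−0.41, SE 0.16). This spread does not decide whether a lower share was the only reason, since expression of these genes in other sorted cells was not tested. Siglech and Slc2a5 were low in every library, controls included. Sall1 and Sall3, of the same list, were too low to test, at no more than 0.383 and 0.207 CPM. Fcrls, in contrast, was at 568 and 666 CPM in the controls, so the list does not show how large a share of microglia the sort held. A contribution of a lower share cannot be told apart from a change within the cells, because the libraries carry no count of cell types. The dendritic list had 14 of 15 tested genes above 0 (median 0.97). For the same reason, the shares of dendritic cells and monocytes among the sorted cells could not be tested.

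The third pattern is the fall of Fkbp5, a glucocorticoid receptor target, by 1.09 on the log2 scale. Lower glucocorticoid signalling is a candidate explanation, and a list of 24 other targets of the receptor was written after Fkbp5 had been seen. Of its 23 tested genes, 16 were below 0 and 0 passed the threshold, with a median of −0.12, a camera p of 0.00378 at the preset correlation and of 0.120 with an estimated correlation (unadjusted, the list being tested alone). Sgk1 (−0.66, adjusted p = 0.0523) and Cd163 (−0.64, adjusted p = 0.0540) lay lower while Cebpd (0.91, adjusted p = 0.0537) lay higher, so the hypothesis stays open.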
